A study of Homo sapiens with 9 samples.

How the data were processed

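In situ chromosome conformation capture (Hi-C) libraries were made from LF1 cells, human diploid lung fibroblasts, in 3 states with 3 replicates each, 9 samples in all. Per the labels' protocols, cells were crosslinked with formaldehyde and libraries were prepared with a commercial Arima kit. Proliferating cells were taken at 60% to 80% confluency, quiescent cells were contact inhibited and then kept without serum for 1 to 2 days, and senescent cells had been out of the cycle after replicative exhaustion for 3 to 4 months. Reads were processed with Juicer 1.6 on hg38, per the submitters' processing notes. The authors deposited 1 loop list and 1 subcompartment list per state and several tables that pair states. No column belongs to a single replicate, whether the replicates were pooled is not stated, and the depth per library is unknown.

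Per the file headers, the loop lists were written by juicer_tools 1.9.9 and hold, for each loop, the observed contact count of the loop pixel and 4 expected counts from its neighbourhood, called donut, bottom-left, horizontal and vertical. Per the file headers, each loop also carries a q-value (FDR) against each expectation and the number of enriched pixels merged into it. Loop anchors are 5, 10 or 25 kb wide. The deposited subcompartment lists give a nested label and a score with 8 ordered levels, from B.2.2 (level 1, most B) to A.1.1 (level 8, most A), on intervals made of 25 kb bins. These labels have the layout of CALDER output, but the caller and its version are not stated. The levels are relative within a chromosome of one map. The pairwise tables hold the pair of levels per 25 kb bin or per run of equal bins, A/B classes at 100 kb from a method that is not stated, and a merge of the proliferating and senescent loop lists at 30 kb.

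Values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plotted with matplotlib 3.10.9. Comparisons cover the 22 autosomes. A bin was compared where both states had a call. It switched when its label went from B to A or from A to B, and the net share is the B to A share minus the A to B share of called bins. Bins with the same call in proliferating and quiescent cells and another in senescent cells were called senescence-only. Bins with the same call in both arrested states and another in proliferating cells were called arrest-shared. Their length was set beside the product of the separate switch shares, each taken among bins with the same proliferating compartment. A loop was shared when both of its anchors overlapped those of a loop in the other list by at least 1 bp. Loop strength is the observed count over the donut expectation. The relative depth of 2 maps is the median ratio of donut expectations at loops with identical coordinates. Loop number ratios have 95% intervals from an exact binomial interval, and named loops have exact Poisson intervals. All intervals cover counting error only.

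Genes are the 18973 protein-coding genes of the 22 autosomes in the RefSeq annotation of GRCh38.p14. Another 153 entries placed on scaffolds, whose positions are not chromosome positions, were left out after a first run had read them as chromosome positions. This table has no strand, so the bin of the gene's midpoint replaced the planned transcription start for compartments, and either gene end within 5 kb of an anchor replaced it for loops. The gene lists and the naming rule were fixed before the data were examined. There were 14 lists: senescence and cell cycle arrest; the senescence-associated secretory phenotype (SASP); DNA replication and mitosis; quiescence and FOXO/KLF; cohesin, CTCF and nuclear architecture; interferon and cytosolic DNA sensing; retrotransposon restriction and DNA methylation; fibroblast matrix; NF-kB and AP-1 regulators; and epithelial, endothelial, blood, neuronal and muscle markers. Another 15 families were taken by symbol pattern: olfactory receptors, ZNF genes, keratins, HOX genes, protocadherins, histone genes, type I interferons, UGT and CYP enzymes, chemokines, collagens, matrix metalloproteinases, ribosomal proteins, solute carriers, defensins, and taste and vomeronasal receptors. The interferon pattern also takes the receptor genes IFNAR1 and IFNAR2. Of 398 listed symbols, 387 were found among the autosomal genes. Named genes are the up to 3 members of a list (2 of a family) that changed compartment with the largest change in level, plus 16 genes given in advance. Named regions are the 5 longest runs of switched bins in each direction. Named loops are those with the highest observed over donut expectation and at least 20 observed counts, up to 2 per list.

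Since each state has 1 call set, no test across states was made and no p-value is given. Each list's mean level change was placed among 10000 random gene lists matched on starting level, and the positions of loop anchors were placed among 1000 circular shifts of the switch labels, both as descriptions of these maps. The measures were tested on simulated data. Of a simulated list in which 49.8% of 9258 loops were kept in place, 49.8% were recovered as shared. In the simulation of the proliferating list thinned to a depth of 0.5, the thinning step recovered 3027 of 3052 loops with exact expectations and 2573 of 3312 loops when the expectations carried noise of 0.2 on the natural log scale. Of 100 simulated lists of 20 genes raised by 1 level between the proliferating and senescent maps, 98 passed the 97.5th percentile, against 1 of 100 unshifted lists.

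Alternatives covered stricter FDRs and enrichment, anchor widths, single-pixel loops, matched depth, the overlap that counts as shared, other expectations, the X chromosome, left-out autosomes, the authors' deposited tables, run length, 4 levels in place of 8, gene body rules and other matched lists. CTCF motifs and base composition were not analysed here, because they need a genome sequence, and the planned continuous compartment rank was not run. X-linked loops were left out of the comparisons and Y-linked features were not used here.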

Results

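Hi-C counts ligations between pieces of DNA that lie close together in the nucleus, and was used here to compare chromosome folding in 3 states of LF1 fibroblasts. The proliferating, quiescent and senescent groups held 3 samples each. Each group was represented by 1 set of subcompartment calls and 1 loop list, so no value has a replicate error and no difference between states could be tested. The called autosomal genome covered 2698 Mb in proliferating, 2702 Mb in quiescent and 2701 Mb in senescent cells. Depth per library was not in the files, but the median observed count at a loop was 76 in the proliferating, 62 in the quiescent and 65 in the senescent list. At loops with identical coordinates the donut expectation in the senescent map was 0.836 times that of the proliferating map, and in the quiescent map 0.502 times. The observed counts at these loops were 0.988 and 0.595 times the proliferating ones, in the same order.

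The comparison of proliferating with senescent cells asked how the nucleus is rearranged when fibroblasts exhaust their divisions. Senescent cells had more of their genome in the A compartment, which holds most genes, than proliferating cells. FOXO1, SESN3 and GAS1, genes of the quiescence and FOXO list, moved from B to A, and the condensin gene NCAPG moved the other way. The endothelial genes EMCN, KDR and SOX17 also moved into A, as did most type I interferon genes, which lie together on chromosome 9. CDKN1A, IL6, IL1A, CXCL8 and COL1A1 were already in the most A-like level and stayed there.

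The A compartment took up 49.1% of called length in proliferating and 57.7% in senescent cells, while the quiescent value was 48.4%. Level A.1.1 alone rose from 22.1% in proliferating to 29.5% in senescent cells. Between proliferating and senescent cells 276.9 Mb moved from B to A (10.3% of bins) and 40.9 Mb from A to B (1.52%). The net share was 8.76% and favoured A on 22 of 22 autosomes, from 2.96% on chromosome 21 to 12.1% on chromosome 13. In the authors' deposited table of 100 kb classes, 5.25% of length moved towards A and 2.22% towards B in this comparison. Of the bins that moved from B to A, 39.2% started in B.1.1 and 7.82% in B.2.2, the most B-like level. The B to A bins held 4.87 genes per Mb, more than stable B (3.06) and fewer than stable A (10.8), and A to B bins held 6.78. In all, 1347 genes moved from B to A and 277 from A to B.

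**Figure D1:**
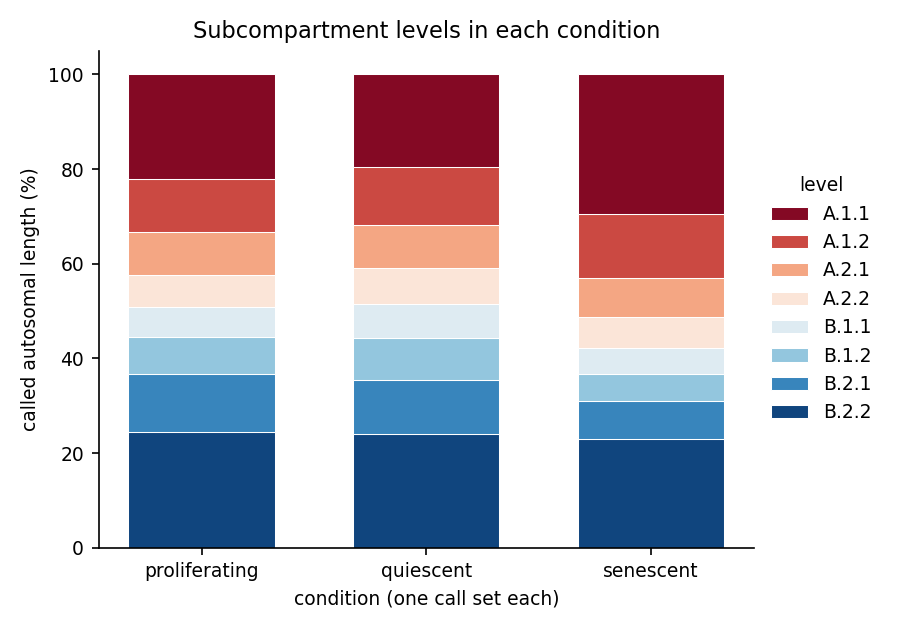
Stacked bars give the share of called autosomal length (%) in each of 8 subcompartment levels for proliferating, quiescent and senescent cells, with 1 call set per state and no error bars. The A.1.1 share was 22.1% in proliferating, 19.6% in quiescent and 29.5% in senescent cells.

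Long runs from B to A in senescent cells lay on chromosome 1 at 188475001 to 190150000 (hg38) with BRINP3, on chromosome 9 at 28800001 to 30200000 with LINGO2, on chromosome 4 at 133875001 to 135200000 with PABPC4L, and on chromosome 11 at 37450001 to 39000000 with no protein-coding gene. The LINGO2 region rose from a mean level of 1 to 6.05. Runs from A to B were shorter, with a median of 50 kb against 175 kb. Among the longest were chromosome 5 at 128200001 to 128700000, which holds FBN2, chromosome 2 at 235775001 to 236225000, with AGAP1, GBX2 and ASB18, and chromosome 8 at 12600001 to 13050000, with LONRF1 and TRMT9B.

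FOXO1 (chromosome 13, 40555667 to 40666641) went from B.2.1 to A.1.1 between proliferating and senescent cells, and its listed loops went from 0 to 2. SESN3 on chromosome 11 went from B.2.1 to A.1.2, and GAS1 on chromosome 9 from B.1.1 to A.1.1 with 1 loop becoming 4. The quiescence and FOXO list rose by 1 level on average, where matched random lists rose by 0.391, and lay above their 97.5th percentile. NCAPG fell from A.2.1 to B.1.1. MCM3 (chromosome 6, 52264015 to 52284742) had A.1.2 and B.2.1 at its midpoint bin, but this switch was lost by the majority of the gene body and by any bin of it. The DNA replication and mitosis list changed by -0.154 levels where matched lists rose by 0.278, below their 2.5th percentile. This mean includes the MCM3 call of -5 levels and was not computed without it. Of the 39 genes, 7 rose and 9 fell. EMCN on chromosome 4 rose from B.2.2 to A.1.1, KDR from B.1.1 to A.1.2 and SOX17 from B.1.2 to A.2.1, and the endothelial list rose by 1.40 levels against 0.535 in matched lists.

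Of 20 type I interferon genes and their receptors, 15 moved from B to A in senescent cells, against 6.01 in matched lists, but these genes fall into 3 clusters. All 15 were IFNA genes, IFNE or IFNW1, of the interferon alpha cluster on chromosome 9. With genes within 1 Mb counted once, the family's mean change of 0.333 lay at percentile 35.9 of matched lists. IFNA1 and IFNA10 went from B.1.2 to A.2.2, the lowest A level, and IFNB1 stayed in A.2.1. In the interferon and DNA sensing list 9 of 40 genes moved to A, among them OAS2, AIM2 and IFI16, but the list's mean rise of 0.725 levels lay inside the middle 95% of matched lists (mean 0.567). The SASP list had no compartment switch in 47 genes, and its level rose by 0.426 against 0.266 in matched lists, inside their middle 95%. MMP1 and MMP3 moved within A, from A.2.1 to A.1.1, and the matrix metalloproteinases rose by 0.8 levels against 0.422. MKI67, outside A in proliferating cells, fell from B.1.1 to B.2.1. CDKN2A and HMGB2 stayed in A.1.2, CCNA2 and DNMT1 stayed in A.1.1, and LMNB1 and IGFBP7 went from A.1.1 to A.1.2.

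Histone genes moved to A at 10 of 79 loci, including H1-1 and H3-7 from B.2.1 to A.1.1, and rose by 0.532 levels against 0.241 in matched lists. Families that moved less than matched genes were olfactory receptors (0.179 against 0.704), ZNF genes (0.39 against 0.693), protocadherins (0.0794 against 0.486), defensins (0.0256 against 0.841), and taste and vomeronasal receptors (0.037 against 0.955). When genes within 1 Mb were counted once, the differences of histone genes, metalloproteinases, protocadherins, and taste and vomeronasal receptors were lost. DEFB103A and DEFB4A moved to B while DEFB103B and DEFB4B moved to A, but these are near-identical copies whose reads are hard to place.

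The mean change of the other lists lay inside the middle 95% of lists matched on starting level. Epithelial markers, keratins, type I interferons and solute carriers lay above the 97.5th percentile when lists were matched on chromosome and A/B instead. Senescence and cell cycle arrest genes rose by 0.0625 levels, with RBL2 moving to A. Cohesin and architecture genes rose by 0.0385, retrotransposon restriction genes by 0.273 with CBX3 moving to A, fibroblast matrix genes by 0.0417, and NF-kB and AP-1 regulators by 0.25. Epithelial markers rose by 0.75 with GRHL2 moving to A, and blood markers by 0.389 with CD3D and CD3E moving to A. Neuronal markers rose by 0.556 with SNAP25 and GAD1 moving to A and OLIG2 to B. Muscle markers rose by 0.467 with FABP4 and SOX9 moving to A and MYF5 to B. The switches of GRHL2 and SNAP25 were kept by the majority of the gene body and lost by the any-bin rule, and that of SOX9 was lost by both rules. Keratins rose by 0.758, HOX genes by 0.41, UGT and CYP enzymes by 1 level, chemokines by 0.575 with CCL19 and CCL25 moving to A, collagens by 0.143, ribosomal proteins by 0.0685 and solute carriers by 0.523.

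**Figure D2:**
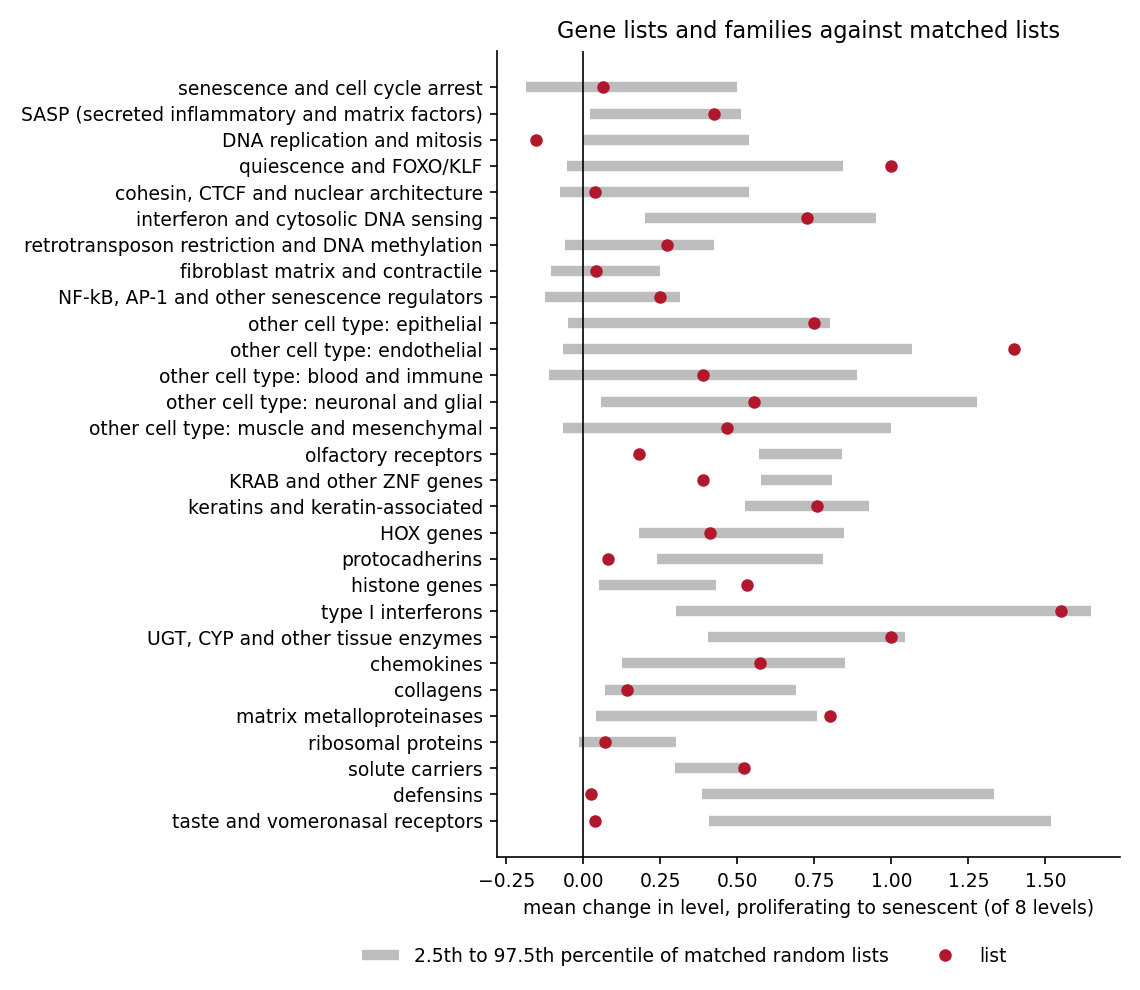
Points give the mean change in level of each gene list or family from proliferating to senescent cells (of 8 levels), and grey bars the 2.5th to 97.5th percentile of 10000 random lists matched on starting level. The endothelial list sits at 1.40 and the DNA replication and mitosis list at -0.154, both outside their bars. The latter mean includes the midpoint call of MCM3.

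The comparison of proliferating with quiescent cells asked which changes come with leaving the cell cycle reversibly. Quiescence moved a similar length of the genome into A as out of it, in more and shorter runs into A. Some histone genes and 8 HOXD genes moved into A, and many keratin genes moved into B. MKI67, a marker of dividing cells, also went to A in quiescent cells, and the lysosomal gene GLB1 went to B.

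In quiescent cells 4.82% of bins moved from B to A (129.9 Mb) and 5.38% from A to B (144.9 Mb). The net share was -0.555%, with 7 autosomes favouring A and 15 favouring B, from -5.81% on chromosome 15 to 3.61% on chromosome 13. A total of 913 genes moved to A and 850 to B. LBR, which encodes the lamin B receptor (chromosome 1, 225401502 to 225428821), had B.2.2 and A.1.1 at its midpoint bin, a switch lost by both gene body rules. GLB1 (chromosome 3, 32961108 to 33097146) went from A.1.2 to B.1.2, CCNG2 from A.1.2 to B.1.1, TERT from A.2.2 to B.1.1 and MKI67 from B.1.1 to A.2.2. GAS1 went from B.1.1 to A.1.2. The switches of GLB1, CDH1, ESRP1 and SYT1 were kept by the majority of the gene body and lost by the any-bin rule.

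SASP genes rose by 0.447 levels in quiescent cells where matched lists fell by 0.142, and fibroblast matrix genes rose by 0.0833 where matched lists fell by 0.284. Both lists lay above the 97.5th percentile without a compartment switch. The interferon and DNA sensing list rose by 0.65 levels in quiescent cells against 0.117 in matched lists, with 6 genes moving to A. Histone genes rose by 0.759 levels, with 9 moving to A, including H1-1 and H3C1 from B.2.1 to A.1.1. Of 39 HOX genes 8 moved from B to A, and these were HOXD3, HOXD4 and HOXD8 to HOXD13. Each rose by 1 level, such as HOXD10 and HOXD11 from B.1.1 to A.2.2. CDH1, ESRP1, KRT5, KRT14, KRT19 and SFTPA1 moved to B among the 20 epithelial markers. With genes within 1 Mb counted once, the interferon and DNA sensing list, epithelial markers and HOX genes lay inside the middle 95% of matched lists. Of 149 keratin and keratin-associated genes 69 moved to B, but the genes form 6 clusters, and with each cluster counted once the family no longer differed from matched genes.

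The longest run from B to A in quiescent cells was on chromosome 6 at 70350001 to 71175000, with FAM135A, SDHAF4, SMAP1 and B3GAT2. The longest run from A to B, on chromosome 5 at 144225001 to 145450000, holds KCTD16 and PRELID2. SYT1 on chromosome 12, HMCN1 on chromosome 1, NRXN3 on chromosome 14 and a ZNF cluster on chromosome 7 at 64500001 to 65525000 also went from A to B.

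The comparison of quiescent with senescent cells asked what separates permanent from reversible arrest. Many of the regions that moved into A in senescence were still in B in quiescent cells. CDH1, many keratins and GLB1 lay in B in quiescent cells and in A in both senescent and proliferating cells. LBR, MKI67 and the HOXD genes went the opposite way, from A in quiescence to B in senescence, the HOXD genes by 1 level. They were in B in proliferating cells too, so for all these genes the quiescent state was the one that differed. The interferon alpha cluster was divided, with some genes in A in both arrested states and others in A in senescent cells alone.

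Between quiescent and senescent cells 12.5% of bins moved from B to A and 3.17% from A to B. The net share was 9.29% and favoured A on 22 of 22 autosomes, but in the authors' deposited table of 100 kb classes the net share was -0.897%. CDH1 (chromosome 16, 68737292 to 68835537) went from B.2.1 to A.1.1, GLB1 from B.1.2 to A.1.1 and FOXO1 from B.1.2 to A.1.1. LBR went from A.1.1 to B.1.2, MKI67 from A.2.2 to B.2.1, and 8 HOXD genes from A to B. The HOXD genes fell by 1 level, with HOXD10 and HOXD11 back at their proliferating level of B.1.1. The switches of CDH1, GLB1 and FOXO1 were kept by the majority of the gene body and lost by the any-bin rule. The longest run from B to A was on chromosome 4 at 133100001 to 136425000, with PCDH10 and PABPC4L. A further run on chromosome 4 at 107025001 to 108575000, with DKK2, PAPSS1, SGMS2, CYP2U1, HADH and LEF1, rose from a mean level of 2.84 to 7.58. NALF1 on chromosome 13 and SHOX2 and RSRC1 on chromosome 3 went from A to B.

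Senescence-only regions covered 203.9 Mb from B to A and 28.5 Mb from A to B. Regions in A in proliferating and senescent cells but in B in quiescent cells covered 132 Mb. Those in B in proliferating and senescent cells but in A in quiescent cells covered 56.9 Mb. Arrest-shared regions covered 73.0 Mb from B to A, against 26.2 Mb if the switches were independent among bins in B in proliferating cells. From A to B they covered 12.3 Mb, against 4.47 Mb among bins in A in proliferating cells. Both comparisons use the same proliferating map, whose errors they share. The expected lengths were not matched on starting level, and bins near the A/B boundary crossed more often in both comparisons. From B.1.1, 63.0% crossed in senescent and 39.6% in quiescent cells, against 3.29% and 1.22% from B.2.2. From A.2.2, 14.8% and 37.8% crossed, against 0.252% and 1.64% from A.1.1. The excess over independence therefore cannot be read as a change common to both arrests. FOXO1, SESN3, EMCN, KDR, OAS2, AIM2 and IFI16 were senescence-only by the 25 kb calls at their midpoints. Of 5 endothelial genes that moved from B to A between quiescent and senescent cells, 2 did so by the any-bin rule. OAS2, AIM2 and IFI16 ended in A.2.2, the lowest A level, as did IFNA1, IFNA10, IFNA14 and IFNA21. GAS1, SOX17, RBL2, CBX3, IFNA1, IFNE and 9 histone genes were arrest-shared. IFNA10, IFNA14, IFNA16, IFNA17, IFNA21, IFNA4, IFNA7 and IFNW1 were in A in senescent cells alone.

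**Figure D3:**
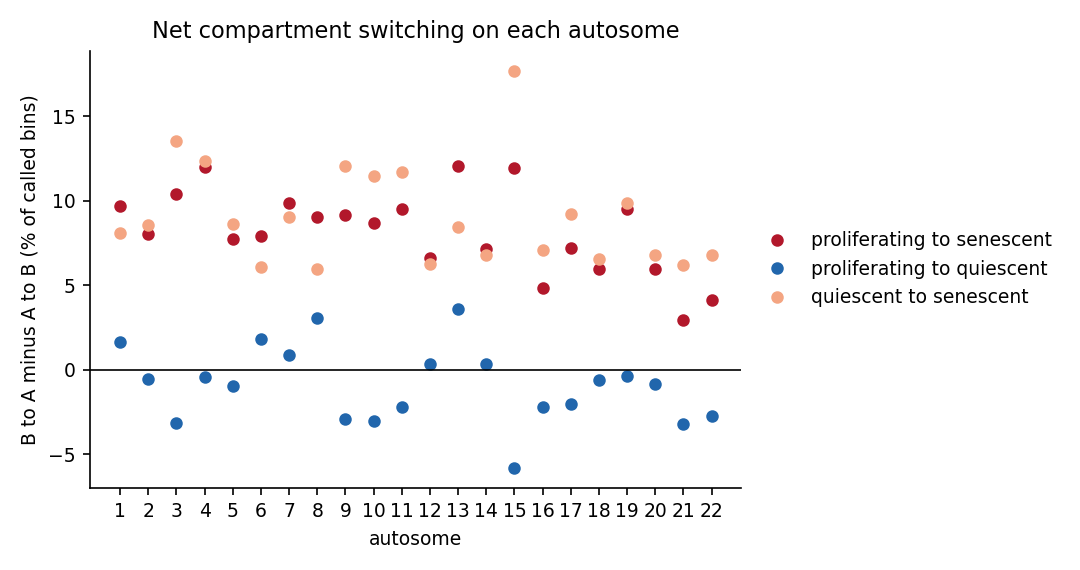
Points give the B to A share minus the A to B share of called bins (%) on each of 22 autosomes for 3 pairs of states. Both comparisons with senescent cells lie above 0 on 22 autosomes, and proliferating to quiescent lies above 0 on 7.

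Chromatin loops were compared next, to ask whether distant contacts are gained or lost in senescence. The senescent list was longer than both others on each of the 22 autosomes. New loops were listed at JAG1, CDKN1C, FOXP2 and LRRTM3, and at protocadherin genes, more of which had a loop in quiescent cells too. Collagen genes gained loops, while fewer histone genes had a loop than in proliferating cells.

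The autosomal lists held 9258 loops in proliferating, 6934 in quiescent and 16585 in senescent cells. The senescent list was 1.79 times as long as the proliferating list (95% interval 1.75 to 1.84), and 1.46 times as long on chromosome 17, where the ratio was lowest. The median loop spanned 290 kb in proliferating, 270 kb in quiescent and 310 kb in senescent cells. Of proliferating loops 44.6% were also listed in senescent cells, and 83.1% with the anchors of both lists widened by 10 kb. Of senescent loops 66.8% were in neither other list, and 48.0% with the same widening. At overlapping loops the observed over donut expectation was higher in senescent than in proliferating cells by 0.32 (median log2 difference), and higher at 83.4% of 4125 loops. At identical coordinates the median observed count was 0.988 times the proliferating one and the donut expectation 0.836 times. The higher strength there came with a lower expectation, not with more raw counts. Depth per library is unknown, so a lower local background cannot be told apart from a shallower map with more contacts for its depth. Senescent loops absent from proliferating cells were weaker than shared ones, with a median of 2.81 against 3.51 at plain overlap and 2.62 against 3.51 with 10 kb widening. Their size order depended on the definition: absent loops were shorter at plain overlap (300 against 330 kb) and longer with 10 kb widening (350 against 285 kb).

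**Figure D4:**
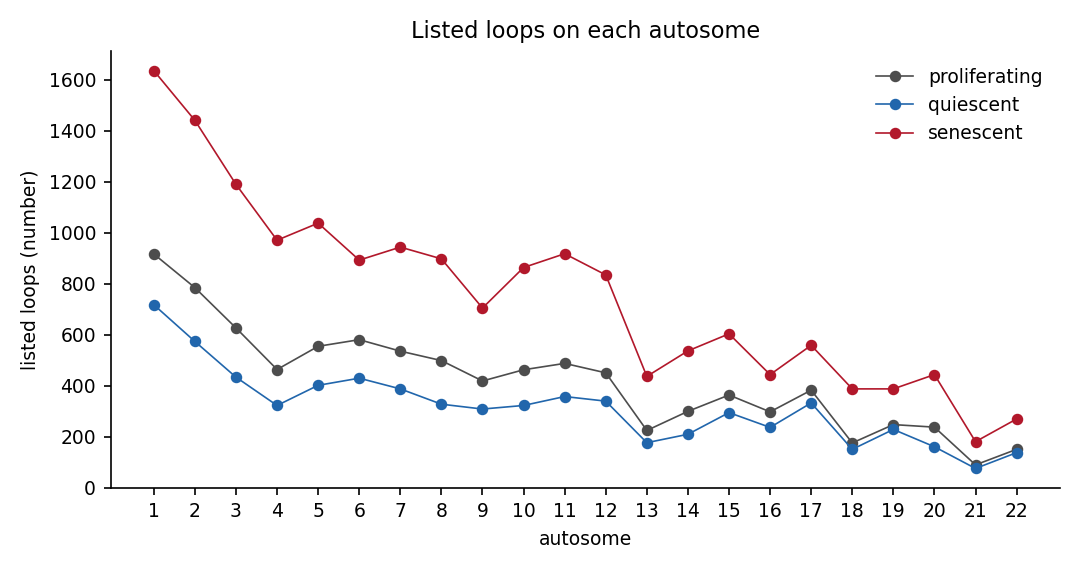
Points give the number of listed loops on each of 22 autosomes in proliferating, quiescent and senescent cells. The senescent list lies above both others on all 22, and the quiescent list lies below the proliferating list on all 22.

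Genes with an end at a loop anchor numbered 6327 in proliferating and 8597 in senescent cells, with 3285 gained and 1015 lost. Chosen after their values were seen, JAG1, LRRTM3 and OR5B21 went from 1 loop to 8, CDKN1C from 1 to 6 and FOXP2 from 1 to 6, while CERS4 went from 4 to 0 and SGIP1 from 6 to 2. Collagen genes with a loop rose from 12 to 26 of 42, above the 97.5th percentile of matched lists, and protocadherins from 8 to 23 of 63. Replication and mitosis genes with a loop rose from 12 to 21 and fibroblast matrix genes from 30 to 40, both inside the middle 95%. Histone genes with a loop fell from 44 to 35, below the 2.5th percentile, and most of these genes lie on chromosome 6, whose local background was also low in senescent cells. Listed loops on chromosome 6 still rose from 581 to 893. Histone genes with a loop also fell in quiescent cells, to 19, where the background of chromosome 6 did not stand apart. Histone genes form 13 clusters and protocadherins 10, so a single anchor can set several genes. The matched lists for loops draw genes one by one and do not account for this.

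A CDKN1C loop of 470 kb had 121 counts and an observed over donut expectation of 4.70 (95% interval 3.90 to 5.62) in senescent cells, with no proliferating loop within 25 kb. Loops of the same kind joined MYC to a site 1200 kb away (4.06, 2.82 to 5.68), PCDH10 to one 330 kb away (4.10, 2.97 to 5.52) and HOXA10 to one 1080 kb away (5.89, 3.91 to 8.51). A loop of 1825 kb on chromosome 6 between 26025001 to 26050000 and 27850001 to 27875000 joined the H2AC4 and H3C2 part of the histone cluster to H1-5 and H2AC16. It had 115 counts and a value of 4.88 (4.03 to 5.86) in proliferating cells and no counterpart within 25 kb in either arrested state, but a loop of 950 kb between H2AC7 and H2AC11 (4.55, 3.72 to 5.50) had one in senescent cells. The strongest listed loops, such as CTAGE15 with CTAGE6 and RGPD1 with RGPD2, mostly lay between duplicated genes. Their donut expectations were low, at 0.711 and 0.542 for these pairs in senescent cells. Reads are hard to place between similar copies, so such entries need not be contacts. Of 30 entries for the strongest loops 25 had a loop within 25 kb in the other list and so were not specific to 1 state, with some loops entered for several comparisons.

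Quiescent cells had fewer listed loops than proliferating cells. Fewer loops were listed at EXT1, ID2 and NR2F1, and fewer histone genes had a listed loop. The quiescent map was also the shallowest, which limits the loops that can be called in it.

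The quiescent list was 0.749 times as long as the proliferating list (0.726 to 0.773) and shorter on 22 of 22 autosomes, but the ratio was 1.05 with the proliferating map thinned to the median quiescent depth. In simulation this thinning removed too many loops of the deeper map, so the direction at equal depth is open. Chosen after their values were seen, EXT1 went from 6 loops to 0, and ID2 and NR2F1 from 6 to 1. Histone genes with a loop fell from 44 to 19 of 79, below the 2.5th percentile of matched lists, but these genes form 13 clusters and were not counted once per cluster. A HOXD10 loop of 1020 kb had a value of 6.87 (5.08 to 9.08) in proliferating cells and no quiescent loop within 25 kb. At overlapping loops the median log2 difference between quiescent and proliferating cells was 0.05, and at identical coordinates it was 0.17. It differed by anchor width, with 0.41 at 5 kb, 0.24 at 10 kb and 0.03 at 25 kb.

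Senescent cells had more listed loops than quiescent cells. MYC had more loops in senescent than in quiescent cells, as did CDH11, HAPLN1 and ID2. Matrix genes such as COL12A1 and THBS1 had strong loops in the senescent list with none nearby in the list of the shallower quiescent map.

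The senescent list was 2.39 times as long as the quiescent list (2.33 to 2.46), but 1.93 and 1.43 times as long with the deeper senescent map thinned to the median quiescent depth under the weaker and the stricter limit, values that lean downward where thinning removes too many loops. Chosen after their values were seen, MYC went from 2 loops in quiescent to 11 in senescent cells, and CDH11, HAPLN1 and ID2 from 1 to 8. A COL12A1 loop of 790 kb had a value of 7.66 (5.77 to 9.97) and a THBS1 loop of 870 kb a value of 7.29 (4.62 to 10.9) in senescent cells, with no quiescent loop within 25 kb. Replication and mitosis genes with a loop rose from 7 to 21 of 39 and fibroblast matrix genes from 26 to 40 of 48, both above the 97.5th percentile of matched lists. At overlapping loops the median log2 difference was 0.25, and at identical coordinates 0.02. By anchor width the latter was -0.14 at 5 kb, -0.03 at 10 kb and 0.17 at 25 kb.

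Loops joined A to A in 65.0% of proliferating, 70.7% of quiescent and 68.2% of senescent loops, and B to B in 18.6%, 13.1% and 18.3%. Anchors of senescent loops absent from proliferating cells were 1.14 times as dense in B to A bins, and 1.31 times as dense in A to B bins, as after circular shifts of the switch labels. Their density was 10.5 per Mb in B to A bins, 12.1 in stable A and 5.48 in stable B. Anchors of proliferating loops absent from senescent cells were 0.904 times as dense in B to A bins and 1.34 times in A to B bins. The excess in A to B bins was therefore not particular to the senescent loops.

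Chromosome 6 stood apart from the other autosomes in the senescent map. The donut expectation at 146 loops with identical coordinates was 0.610 times the proliferating value on chromosome 6, and the median of the other autosomes was 0.852. Between quiescent and senescent cells the ratio was 1.14 on chromosome 6 against 1.59 elsewhere. Between proliferating and quiescent cells chromosome 6, at 0.543, lay within the range of the others.

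**Figure D5:**
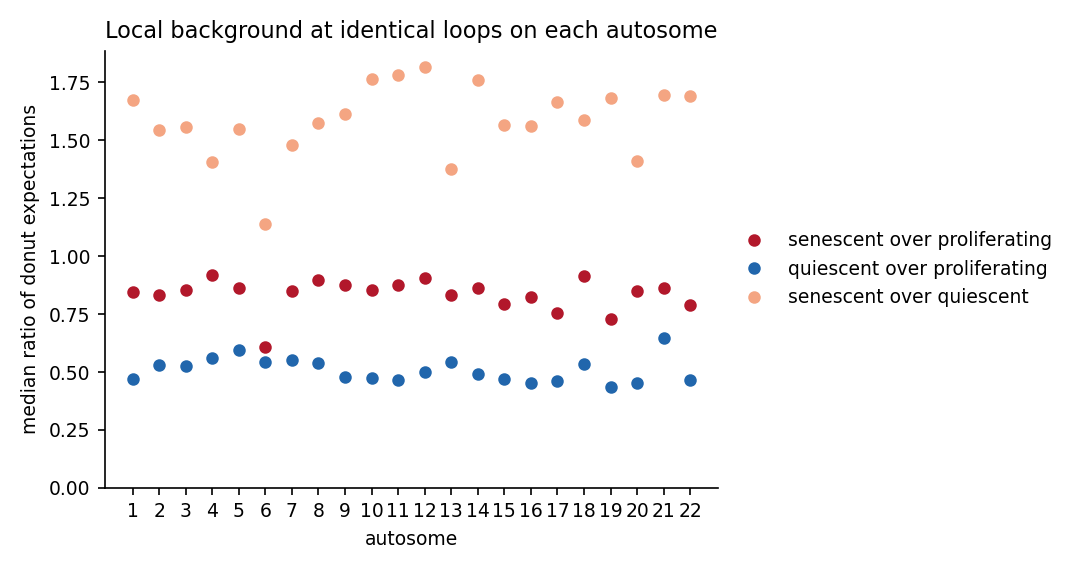
Points give the median ratio of donut expectations at loops with identical coordinates on each of 22 autosomes, for 3 pairs of states. Chromosome 6 is the lowest in both ratios with senescent cells, at 0.610 over proliferating and 1.14 over quiescent.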

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

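In the weighing of the patterns here, the tests of map depth, joined loops, the A/B boundary, the 100 kb classes and chromosome 6 were chosen after the results were seen. The loop number at matched depth was planned before the data were examined with the weakest call as its limit, and its stricter limit was added later.

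The senescent list held 433 loops on the X chromosome, which the comparisons leave out, against 180 in the proliferating and 126 in the quiescent list. It was singled out as a signal in data outside the main measurement. The senescent to proliferating ratio was 2.41 on X and 1.79 on the autosomes, and no explanation was tested.

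The longer senescent loop list was weighed first. A deeper senescent map would raise the local background, but at identical loops the senescent donut expectation was 0.836 times the proliferating one (0.827 to 0.845). The observed counts at these loops were 0.988 times the proliferating ones. Neither value was above that of the proliferating map, which argues against a deeper senescent map at these loops. The expectation is a local background, so it cannot settle total depth. Repeats of single contacts within 10 kb are also argued against, because few were found. Joining such loops left 16410 of 16585 senescent and 9148 of 9258 proliferating loops, at a ratio of 1.79. The lists already had neighbouring pixels merged, so this test could move the ratio little and does not cover repeats further apart. Leaving the cell cycle in itself cannot be told apart: the quiescent to proliferating ratio at matched depth was 1.05 with the weakest quiescent call as the limit and 1.56 with the stricter limit, and in simulation this thinning discarded too many loops of the deeper map when the expectations were noisy. A change tied to senescence remains a hypothesis, with pooling, library quality and replicate spread untested.

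The net move from B to A in senescent cells was weighed next. An A/B boundary set lower in the senescent calls cannot be told apart from a real move: with the lowest senescent A level counted as B the net share from proliferating cells fell from 8.76% to 2.31%, but that fall is the share of this level by construction, while 87.1% of the B to A bins rose at least 2 levels and 37.6% ended in the lowest A level. The 25 kb caller alone is argued against for the direction from proliferating to senescent, since the authors' deposited table of 100 kb classes gave 3.03% with 20 autosomes favouring A, but not for the extent, as that table put 33.9% of the 25 kb B to A bins towards A and 44.8% in stable B. For quiescent to senescent the separate 100 kb classes of that pair gave -0.897%, with 6 autosomes favouring A. The caller may account for that part of the pattern. These classes put 21.4% of the 25 kb B to A bins towards A, 41.0% in stable A and 37.2% in stable B. The 2 sets of 100 kb classes gave the same senescent state on 90.7% of length. Both net shares are small beside the part where the sets differ, which limits what either can show. Whether senescence itself opens these regions stays open.

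The low background on chromosome 6 in senescent cells was weighed last. The expectation model alone is argued against, as the observed counts fell too, to 0.732 of the other autosomes (0.689 to 0.770). A single region is argued against, as the highest of the 8 windows of 20 Mb with at least 5 identical loops reached 0.841, though a last window with 2 loops stood at 1.09. Fewer copies of chromosome 6 in part of the senescent cells may explain a background of 0.716 relative to the other autosomes (0.689 to 0.748), with chromosome 6 lowest of 22 in both comparisons with senescent cells and not between proliferating and quiescent cells. This is a hypothesis from the same data, and no read depth per chromosome was used here.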

How the results depend on the processing

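No paired analysis was possible because each state has 1 call set and no column belongs to a replicate.

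The senescent to proliferating loop number of 1.79 became 2.01 with loops observed at least 2 times each expectation, and at matched depth 1.83 with the weakest call and 1.95 with the 95th percentile call as the limit, an alternative added later. The quiescent to proliferating number of 0.749 became 0.860 with observed at least 2 times each expectation, 0.830 with anchors of 10 kb or wider, 0.516 with 5 kb anchors and 0.672 with at least 2 merged pixels. It reversed at matched depth, to 1.05 with the weakest call and 1.56 with the added 95th percentile call. Thinning removes too many loops of the deeper map when expectations are noisy, so the values at matched depth above lean upward. Depth was matched on 1 median, and the maps were not brought to equal depth at every scale. The senescent over quiescent expectation, 1.57 at the median, was 1.33 at 25 kb and 1.88 at 5 kb anchors, and 1.25 for loops over 500 kb and 1.85 for loops under 200 kb. The senescent to quiescent number of 2.39 became 2.15 with anchors of 10 kb or wider, 3.54 with 5 kb anchors, 2.72 with at least 2 merged pixels, and 1.93 and 1.43 at matched depth with the same 2 limits, where the lean is downward because the senescent map is the deeper one.

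The share of proliferating loops listed in senescent cells, 44.6%, became 25.9% with identical midpoints, 83.1% with anchors widened by 10 kb and 87.2% with 25 kb. Senescent loops listed in proliferating cells (24.9%) became 14.5%, 46.7% and 50.3% in the same order. Quiescent loops listed in proliferating cells (40.5%) became 21.8%, 71.1% and 75.6%. Senescent loops listed in quiescent cells (17.95%) became 7.95%, 32.7% and 36.7%, and 18.8% for loops that pass at the shallower depth, which does not apply to senescent loops sought in the deeper proliferating map. The median size ratio of senescent over proliferating loops, 1.07, became 1.21 with 5 kb anchors only, and that of quiescent over proliferating, 0.931, became 0.8 with 10 kb and 0.762 with 25 kb anchors only.

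Loop strength in senescent over proliferating cells (log2 0.32) became 0.29 with the bottom-left, 0.25 with the horizontal and 0.27 with the vertical expectation, and 0.24 at identical coordinates. Quiescent over proliferating (0.05) became 0.0754 with the horizontal and 0.0750 with the vertical expectation, and 0.17 at identical coordinates. Senescent over quiescent (0.25) became 0.23, 0.17 and 0.18 with the 3 other expectations and 0.0231 at identical coordinates. With only gene ends inside an anchor, the ratio of genes at loops became 1.495 from 1.36 for senescent over proliferating and 0.989 from 0.940 for quiescent over proliferating cells.

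The A share counted over protein-coding genes was 75.1% in proliferating, 75.4% in quiescent and 80.7% in senescent cells. With the X chromosome added it was 48.7% of length in proliferating and 56.7% in senescent cells. The net share to A from proliferating to senescent cells, 8.76%, became 3.03% in the authors' deposited table of 100 kb classes, 2.31% with senescent A from A.2.1 upwards (added later), 8.05% for changes of at least 2 levels, 8.14% with the X chromosome and 8.52% at the lowest with 1 autosome left out. From proliferating to quiescent cells, -0.555% became -1.29% for runs of at least 100 kb and -0.334% with the X chromosome, and ranged from -0.756% to -0.352% with 1 autosome left out. From quiescent to senescent cells, 9.29% reversed to -0.897% in the authors' deposited table of 100 kb classes. It became 2.85% with senescent A from A.2.1 upwards (added later), 9.68% for runs of at least 100 kb, 8.84% for changes of at least 2 levels and 8.46% with the X chromosome, and ranged from 8.96% to 9.50% with 1 autosome left out.

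With 4 levels, the mean level change became 0.487 from 0.502 (proliferating to senescent), -0.0105 from -0.0353 (proliferating to quiescent) and 0.497 from 0.538 (quiescent to senescent). With changes of at least 2 levels, senescence-only bins became 6.46% from 7.57% (B to A) and 0.571% from 1.06% (A to B), and arrest-shared bins 1.62% from 2.71% and 0.214% from 0.458%.

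Of 114 alternatives to the comparisons, 44 left the result within its counting interval, 67 moved it and 3 reversed it. For single gene lists, 134 of 156 alternatives left a gene count within 1.5 times its value or a percentile outside the middle 95% on the same side. Within that tolerance counts did change, such as epithelial genes to B in quiescent cells from 6 to 4 with any bin of the gene body. Counting genes within 1 Mb once moved 12 and reversed 3 of 28 list results: protocadherins from proliferating to senescent cells (percentile 56.4), keratins from proliferating to quiescent (55.7) and keratins from quiescent to senescent cells (13.5). Matching on chromosome and A/B moved 4 of 28. These counts cover lists outside the middle 95% of the first match only. With the second match, lists inside it also moved out: epithelial markers, keratins, type I interferons and solute carriers upward from proliferating to senescent cells, and protocadherins downward from proliferating to quiescent cells. From quiescent to senescent cells metalloproteinases and solute carriers moved out upward, and SASP, histone and chemokine genes downward. Of the 193 list and family genes that switched from proliferating to senescent cells, 186 did so by the majority of the gene body and 180 by any bin of it; of 254 from proliferating to quiescent cells, 246 and 230, and of 316 from quiescent to senescent cells, 306 and 283. Motif, sequence and continuous-rank results were not run.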
